A study of Mus musculus with 8 samples.

How the data were processed

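The data were H3K27ac chromatin immunoprecipitation libraries and input libraries from mouse spleen B cells labelled 0 h or 48 h, 2 libraries in each of 4 groups. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated and H3K27ac was precipitated with a polyclonal antibody. Per the submitters' processing notes, the reads belong to build mm10 (GRCm38), and bcl2fastq 2.20.0.442, Bowtie 1.1.2, Picard 2.7.1, HOMER and edgeR are named, with no role or order stated. How the regions were defined, how duplicates were treated and what edgeR was used for are not given in the sources used here. The authors deposited a single table of 75148 regions whose values are, by its name, quantile normalised counts. These deposited values are whole numbers with nearly the same sorted values in all 8 libraries, and they were treated as a score: quantile normalised read counts and not raw counts. All 8 columns of values were used, and each matched the title of 1 sample.

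Quantile normalisation removes the total count, so the depth per library is unknown, no counting interval or limit of detection can be given, and a global change of the mark would not be visible. As H3K27ac and input were normalised together, a region of input can have a value as high as a peak of H3K27ac. The regions were 500 to 101148 bp long (median 954, in total 157 Mb, 22368 of them of the shortest length), and longer regions have higher values and were called more often: 2.58% of the regions of 500 bp and 54.3% of those over 5 kb.

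Groups were taken from the titles. In 4 samples the library name in the description names the other condition, and grouping by these names was an alternative fixed beforehand. The main test was limma 3.58.1 in R 4.3.3: lmFit and eBayes with a mean trend on log2 of the value plus 1, the 2 H3K27ac libraries labelled 48 h against the 2 labelled 0 h, two-sided, with Benjamini-Hochberg adjustment over all regions and a threshold of 0.05. The input comparison used the same test with 4 group means over the 8 libraries, and the difference of the H3K27ac change from the input change was an interaction contrast of that fit. The count test written for raw counts was not used, since the values are not raw counts.

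Coordinates are as the deposited table gives them; its counting convention is not stated. Genes were the protein-coding and constant-region genes of the RefSeq table of GRCm38.p6. A region belonged to every gene it overlapped, or else to the nearest gene within 50 kb; 7863 regions had none, and 15284 genes had a region. Neighbouring genes can thus share a region, and a gene with many short regions of low value has a mean that can differ from its strongest region. The gene shown for a region is the gene with the largest overlap. The table gives no strand, exons or UTRs, so transcription start sites were not known: where the plan named them, either end of a gene was used instead, with 1 kb for regions near gene ends (2.5 kb as an alternative) and 2.5 kb for the clusters. Exons, introns and UTRs are therefore not stated for any region. The direction of called regions near and away from gene ends was compared by Fisher's exact test. Superenhancer-like clusters were stitched at gaps of up to 12500 bp and ranked by the sum of the group mean values.

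The 17 gene lists held 406 entries, of which 404 matched the gene table. As Igj and Emr1 are former names of the members Jchain and Adgre1, and each was counted once, fewer genes remained, and 383 list members had a region. They were tested with limma camera at a preset correlation of 0.01, and again with an estimated correlation. A rule for named regions and genes was fixed beforehand. It took every region of the Aicda locus, the 12 largest rises and the 12 largest falls past the threshold whose libraries did not overlap between groups (1 region per gene, leaving out predicted genes and small RNAs), the 2 highest and 2 lowest members of each list, and the gene of any count of 5 or fewer. Other members that rose or fell, named beside them, and the regions of the Igh locus were chosen after their values were seen. A further list of 23 genes of the handling response was written before its values were examined, except that of Nfil3, a member of the IL-4 list.

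The fit was tested on simulated data of 75148 regions with 4 libraries. Of 50 regions each with a true change, it found 2% at 1.5-fold, 44% at 2-fold, 70% at 4-fold and 86% at 8-fold. It also called 14 of 74948 unchanged regions. With 200 changed regions in that simulation, these 14 were a larger share of its calls than the adjusted threshold aims at. With 15000 changed regions, 3.78% of 12271 calls were unchanged regions. The simulated noise was normal and independent between regions, with the spread that the fit itself estimated for each region. It held no deviation shared by the regions of a library, so these shares do not give the error rate of the real calls. Alternatives fixed beforehand were pseudocounts of 0.5 and 8, leaving out the lowest 25% or 50% of regions, cyclic loess normalisation, median centring, eBayes without a trend or robust, a replicate block, grouping by library name, leaving out each library, a test against a 1.5-fold change, and all 8 libraries in the fit. For the lists they were an estimated correlation, the region nearest a gene end and the region with the highest value. For the clusters they were a gap of 5 kb and keeping all regions. Alternatives added after seeing the data were keeping only regions with more H3K27ac than input, leaving out the 2 H3K27ac libraries with conflicting names, leaving out each H3K27ac library in the fit of all 8 libraries, giving each region to the gene with the nearest end, and the cluster on the other side of Aicda. The filter on H3K27ac above input compared means of log2 values over both times. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.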

Results

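H3K27ac, the acetylation of histone H3 at lysine 27 that marks active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in mouse spleen B cells of the C57BL/6J background whose floxed Tet2 and Tet3 genes were labelled wild type. The cells were labelled 0 h (unstimulated) or 48 h (activated with lipopolysaccharide at 25 ug/mL and interleukin 4 at 10 ng/mL, a treatment known to drive switching of the immunoglobulin class). There were 4 groups of 2 libraries each: H3K27ac at 0 h, H3K27ac at 48 h, and input chromatin at 0 h and at 48 h. The deposited table gave a normalised read count for each of 75148 regions in the 8 libraries, on build GRCm38 (mm10). The values had been quantile normalised over H3K27ac and input libraries together, so that each library had a median of 18 or 19 and a sum between 6472449 and 6480274. The sequencing depth of each library was therefore unknown, and a global gain or loss of the mark could not be seen. In 4 of the 8 samples (0 h replicate 2 and 48 h replicate 1, H3K27ac and input) the library name in the description named the other condition than the title, the source name and the time point. Groups followed the titles, and every direction below is that of the libraries labelled 48 h by title against those labelled 0 h by title. The labels did not say whether replicates came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

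The first comparison asked where H3K27ac differed between activated and resting B cells. Of the 75148 regions, 7611 had higher and 6958 had lower H3K27ac in the libraries labelled 48 h at an adjusted p below 0.05 (limma on log2 of the value plus 1, Benjamini-Hochberg over all regions). The median fold among regions called higher was 2.33. The largest rise was in a region on chromosome 4 from 126000433 to 126007697, which lay 15744 bp from Csf3r, the gene of the granulocyte colony-stimulating factor receptor. Its value went from 29 ± 0 to 571.5 ± 0.707 (SD, n = 2 libraries each), a log2 change of 4.25 with a standard error of 0.13 and an adjusted p of 0.000381. A region of 48474 bp on chromosome 13 from 52786632 to 52835106, which ended 1 bp from Auh, went from 382 ± 15.6 to 5106 ± 291, a 13.3-fold rise with an adjusted p of 0.000381. A region of chromosome 15 from 81648997 to 81654415 that overlapped Ep300, which encodes an acetyltransferase known to place this mark, went from 21.5 ± 0.707 to 311 ± 0, a 13.9-fold rise. The other 9 regions named by the rule as the largest rises had log2 changes from 3.70 to 4.05. Of these, the regions of Kctd1, Cldn13, Glp2r, Marchf10, Lrrc7 and Nostrin overlapped the gene. The remaining 3 lay 11759 bp from Slc31a2, which encodes a copper transporter, 8196 bp from Ercc6l2 and 10975 bp from Shprh, which both encode helicase-like proteins.

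The largest fall was in a region on chromosome 7 from 19312940 to 19328574, 2822 bp from Fosb, an AP-1 transcription factor gene induced early by many stimuli. Its value went from 1774 ± 240 to 155 ± 12.7, 11.3-fold lower at 48 h, with a log2 change of -3.50, a standard error of 0.13 and an adjusted p of 0.000475. The region 7837 bp from Cmc2 was 8.09-fold lower, the region within Asph 7.62-fold lower, and the region overlapping Il1r1, the interleukin 1 receptor gene, 7.24-fold lower. The other 8 of the 12 largest falls had log2 changes from -2.91 to -2.79. Those assigned to Ebf3 and Asmt overlapped the gene, and those assigned to Adgrd1, Ldlrad3, Nyx, Rasgef1b, Rhou and Spaca1 lay 14254, 21224, 3608, 40309, 31428 and 33734 bp from it. Several of these falls came from low values: the region nearest Rhou went from 16.5 ± 0.707 to 1.5 ± 0.707, and that nearest Rasgef1b from 24 ± 8.49 to 3 ± 2.83. At Ldlrad3, Spaca1 and Nyx the change did not differ from that of input at the threshold (adjusted p = 0.0553, 0.0648 and 0.0697 for the difference). Fold changes on the scale of log2 of the value plus 1 understate the change of such regions.

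**Figure D1:**
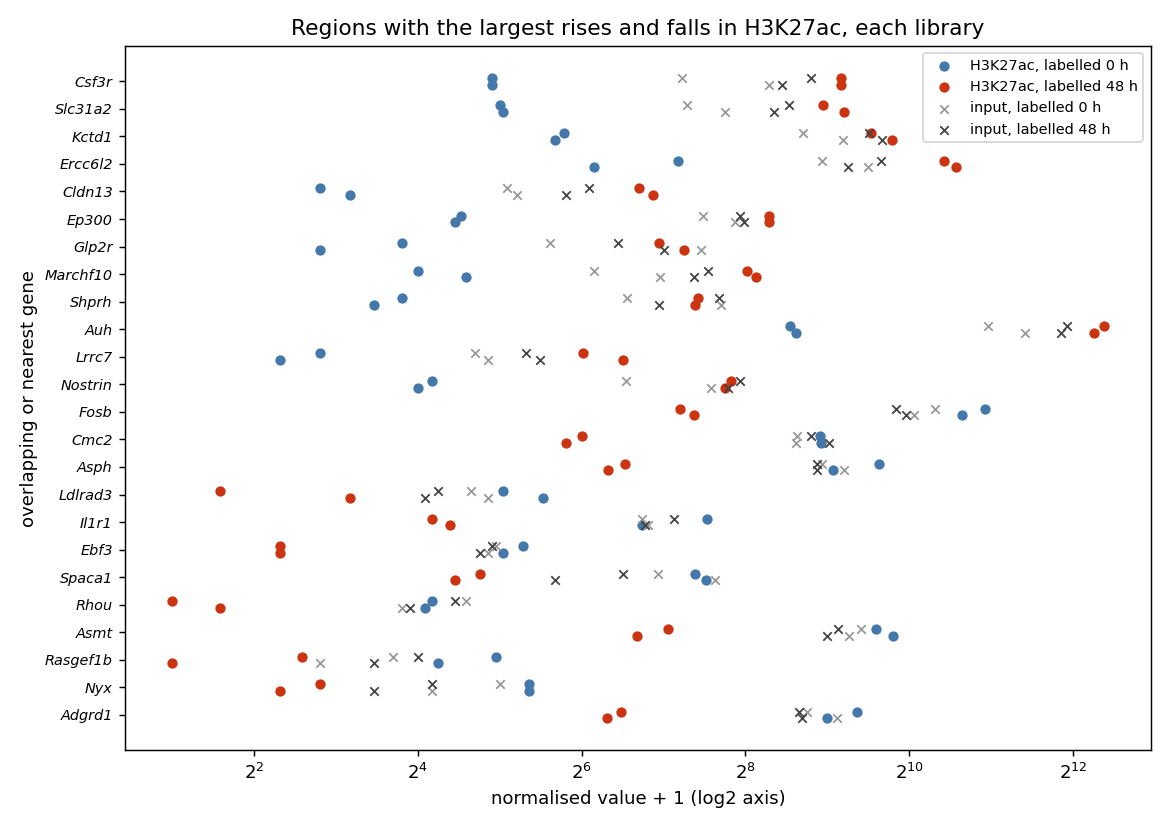
Normalised values plus 1 on a log2 axis, for each library, of the 12 regions with the largest rises (upper rows, Csf3r to Nostrin) and the 12 with the largest falls (lower rows, Fosb to Adgrd1). Circles are H3K27ac and crosses input libraries; in each region the H3K27ac libraries of the labels do not overlap, as the rule required, as at Csf3r with values of 29 and 29 against 572 and 571, but libraries of the same label can lie apart, as at Ercc6l2 with 144 and 70 at 0 h and at Rasgef1b with 5 and 1 at 48 h, while input values lie mostly near the higher of the H3K27ac groups.

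These calls were limited by the number of libraries. When any 1 of the 4 H3K27ac libraries was left out of the fit, 0 regions were called in either direction, and with all 8 libraries in the fit, to share an estimate of spread, leaving out an H3K27ac library gave 1963 to 2546 regions higher and 1343 to 1996 lower. In the latter fit the region nearest Rasgef1b lost its call without 0 h replicate 1 or 48 h replicate 2, and the other 23 named regions kept theirs. Grouping the 4 libraries by the names in the descriptions instead of the titles called 0 regions. Without a mean trend in eBayes, 2418 regions were higher and 1436 lower, and 1677 and 946 against a 1.5-fold change. The balance of higher and lower regions depended on scaling and filtering: median centring gave 6608 higher and 8271 lower, and leaving out the lowest 50% of regions 8182 and 8517.

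Regions near gene ends were called more often in both directions than regions further away (27.2% against 17.6%). Among called regions, those near gene ends had more often risen. Within 1 kb of either end of an annotated gene, 2209 of 13951 regions were higher and 1589 lower in the libraries labelled 48 h, so that 58.2% of called regions had risen. Further away, 5402 of 61197 regions were higher and 5369 lower, or 50.2% risen. The odds ratio was 1.38 (95% interval 1.28 to 1.49, Fisher's exact test p = 1.78e-17, two-sided); it was 1.2 (p = 0.0625) when the calls came from eBayes without a mean trend and 1.16 (p = 0.138) when they came from a test against a 1.5-fold change. Regions are not independent replicates, so this p describes the regions of these libraries. The odds ratio was 0.895 when the calls came from the fit of all 8 libraries without 0 h H3K27ac replicate 1, which turned its direction, and 1.06 without 48 h H3K27ac replicate 2. Without the 2 H3K27ac libraries with conflicting names, which left 1 H3K27ac library per group, it was 2.28. With only regions with mean H3K27ac above mean input, it was 1.15 (Fisher's exact test p = 0.0224).

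The title of the series concerns Aicda, which encodes the cytidine deaminase AID that starts class switching and somatic hypermutation, and its superenhancer. Aicda lies on chromosome 6 from 122553809 to 122564180. Of 17 regions within 50 kb of it, 7 had higher H3K27ac in the libraries labelled 48 h and 0 had lower, and the same number passed when adjusted over the locus alone. The 7 became 4 against a 1.5-fold change, 1 when only regions with mean H3K27ac above mean input were kept, and 3 without the H3K27ac libraries with conflicting names. All 7 lay over Aicda or at lower coordinates, towards and over Mfap5. This filter compared means of log2 values over 0 h and 48 h together. By that measure, of the 7, only the region from 122518950 to 122519450, within Mfap5 and 34359 bp from Aicda, had mean H3K27ac above mean input. The filter on input thus left out the called regions over and nearest Aicda. As it averages both times, a region that rises from a low value at 0 h can fail it. The region from 122540762 to 122549010, 4799 bp from Aicda, rose most, from 40.5 ± 10.6 to 328 ± 4.24 (SD, n = 2 each), 8.06-fold, with a log2 change of 3.01, a standard error of 0.20 and an adjusted p of 0.000877. The region from 122552633 to 122560709, which covers the lower-coordinate end of Aicda, rose 3.76-fold from 108 ± 1.41 to 411 ± 62.2 (adjusted p = 0.00115). The region of 14455 bp from 122524331 to 122538786, which overlaps Mfap5, rose 4.48-fold from 180 ± 12.7 to 810 ± 38.2 (adjusted p = 0.000714).

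The other 4 regions that rose were shorter and weaker. They started at 122518950, 122519736, 122522068 and 122539288, and had values of 16 to 43.5 in the libraries labelled 48 h. On the higher-coordinate side, none of the 9 regions of the Aicda locus passed the threshold (limma; the region from 122587230 to 122587730 within Apobec1 alone had an unadjusted p below 0.05, and its adjusted p was 0.118). There the region from 122568841 to 122572534, 4661 bp from Aicda, went from 128 ± 11.3 to 103.5 ± 0.707 (adjusted p = 0.185). The region from 122596530 to 122605353, which overlaps the neighbouring cytidine deaminase gene Apobec1, had the highest 0 h value of the locus and hardly differed, with 677.5 ± 58.7 at 0 h and 707 ± 24 at 48 h (adjusted p = 0.71). At 0 h the 3 long regions that rose lay below input, and at 48 h near it: input went from 605 ± 153 to 796.5 ± 6.36 over Mfap5, from 246 ± 70.7 to 410 ± 31.1 below Aicda and from 346.5 ± 53 to 389.5 ± 54.4 over Aicda. The 3 long regions kept an adjusted p below 0.05 when any H3K27ac library was left out of the fit of all 8 libraries, with log2 changes of 2.75 to 3.27 for the region 4799 bp from Aicda, but 0 of the 7 did in the fit of the H3K27ac libraries alone. The regions that started at 122518950, 122519736 and 122539288 lost the call in at least 3 of those 4 fits.

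**Figure D2:**
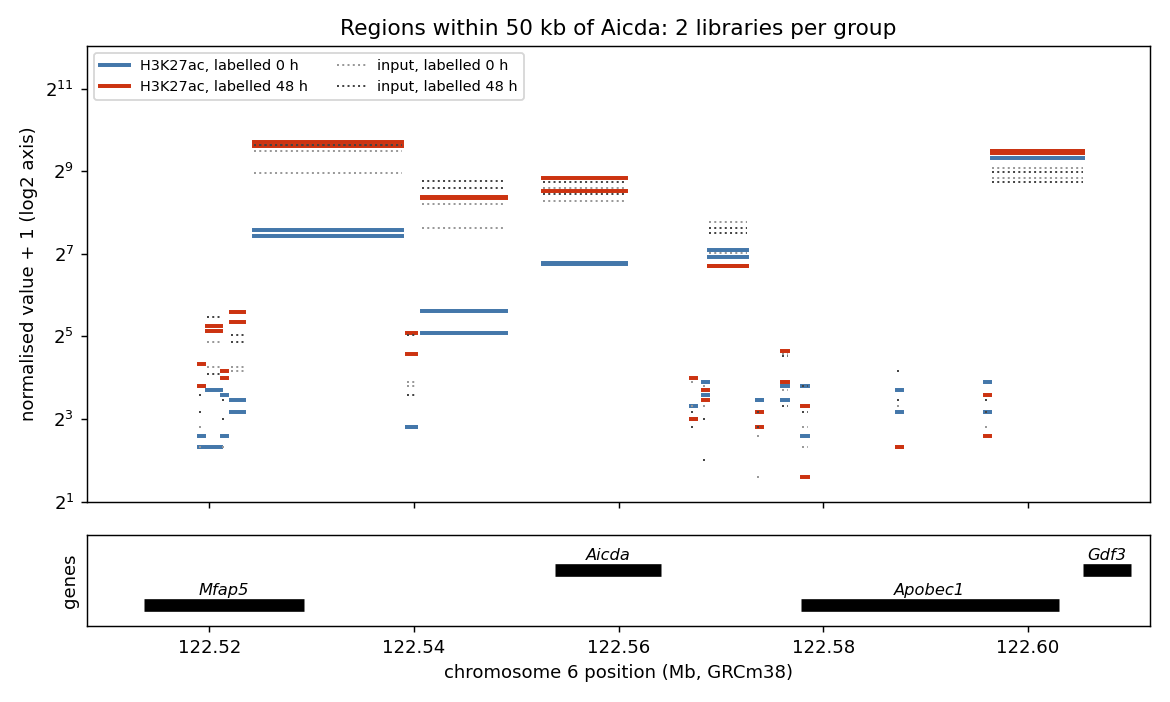
Regions within 50 kb of Aicda on chromosome 6 (position in Mb), each drawn to scale as a line at its normalised value plus 1 on a log2 axis, 1 line per library (solid H3K27ac, dotted input), above the annotated genes. H3K27ac lines of 48 h lie above those of 0 h over Mfap5, between Mfap5 and Aicda and over the start of the Aicda interval, and overlap or lie close together from there to Apobec1.

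To describe the locus as a superenhancer-like unit, regions further than 2.5 kb from any gene end were stitched where gaps were at most 12500 bp and ranked by summed H3K27ac. This gave 17978 clusters and placed different clusters on the 2 sides of Aicda. On the lower-coordinate side, the cluster from 122539288 to 122549010 covered 9174 bp in 2 regions; its summed value was 46.5 at 0 h (rank 8061, mean of 5.1 per kb) and 356 at 48 h (rank 1800, 38.8 per kb). The nearest cluster, from 122567035 to 122574020 on the other side, covered 5193 bp in 4 regions and had 158.5 at 0 h (rank 3770, 30.5 per kb) and 132.5 at 48 h (rank 4120, 25.5 per kb). Input lay above H3K27ac in both clusters at both times, with sums of 259.5 at 0 h and 431.5 at 48 h on the lower-coordinate side and 199.5 and 208 in the nearest cluster. The plan named the cluster at Aicda without saying on which side; both clusters were chosen after region values of the locus had been seen, the lower-coordinate one after those of the nearest. The rule on gene ends left out the long regions that rose over Mfap5 and over Aicda, as each spans a gene end. With regions near gene ends kept, all 17 regions joined in a single cluster of 51590 bp of covered sequence. It ranked 1116 of 20087 at 0 h and 469 at 48 h. Its summed H3K27ac was 1241.5 at 0 h, below input at 1997, and 2564 at 48 h, above input at 2417.5. No test was made of these ranks.

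Of 17 gene lists fixed before the data were examined, 5 were higher and 1 was lower in the libraries labelled 48 h (limma camera with a preset correlation of 0.01, Benjamini-Hochberg over the lists). The same test called 0 lists higher and 4 lower under the grouping by library name, which called 0 regions. That grouping sets replicate 1 against replicate 2 with the titles balanced. The lists called lower included IL-4 and STAT6 response (median -0.05, camera adjusted p = 0.0287) and NF-kappaB and LPS response (-0.11, 0.00345). A list can thus be called where no region is and where the groups do not differ by title. A call at the preset correlation alone therefore does not show an effect of activation. With only regions whose mean H3K27ac lay above mean input, 2 lists were higher and 0 lower. With a correlation estimated from the data, none of the 17 passed (adjusted p of at least 0.686). With 2 libraries per group this estimate had little to rest on and the test little power. Its failure to pass therefore says little about any list. Each gene had as its value the mean log2 value of the regions that overlapped it or, for regions that overlapped none, lay nearest it within 50 kb. Of all 15284 genes, 3134 were higher and 2056 lower (34% called, of which 60.4% were higher). Among cell cycle genes 25 of 35 rose and 0 fell, with a median log2 change of 0.58 (camera adjusted p = 1.9e-06; adjusted p = 0.686 with an estimated correlation). Adjusted over the list alone, 26 rose and E2f3 alone fell. Ccnb2, a mitotic cyclin, rose by a log2 change of 1.76 (standard error 0.17, adjusted p = 8.5e-05) and Plk1, a mitotic kinase, by 1.57. The lowest members were Mki67 at -0.33 and E2f3 at -0.46, which did not pass over all genes, and these had changes of 1.16 and 0.71 at the region with the highest value of each gene.

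Cholesterol synthesis genes rose with 11 of 19 measured members, the same count adjusted over the list alone, and 0 fell (median 0.59, camera adjusted p = 0.000612; adjusted p = 0.686 with an estimated correlation). Idi1 rose by 1.69 and Fdps by 1.60, both enzymes of isoprenoid synthesis, while Mvk was at -0.01 and Srebf2 at 0.04. Of the 30 genes of MYC targets, ribosome biogenesis and metabolism, 12 rose and 0 fell (median 0.38, camera adjusted p = 0.000612; adjusted p = 0.686 with an estimated correlation). Adjusted over the list alone, 13 rose and Psat1 alone fell. Shmt2, a mitochondrial enzyme of 1-carbon metabolism, rose by 2.12 and Srm, spermidine synthase, by 1.82. Phgdh was at -0.44 and Psat1 at -0.58, the latter being 0.86 at the region with the highest value.

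Genes of the IL-4 and STAT6 response rose in 11 of 24 cases and fell in 2, the same counts as adjusted over the list alone (median 0.31, camera adjusted p = 0.00458; adjusted p = 0.686 with an estimated correlation). Cish, an inducible inhibitor of STAT signalling, had the largest change of the members of any list, 9.08-fold (log2 change 3.18, standard error 0.07, adjusted p = 1.52e-09). Il4i1, an amino acid oxidase induced by interleukin 4, rose 3.57-fold. Gfi1 was 1.69-fold and Hs3st1 1.54-fold lower. Interferon response genes rose in 13 of 20 cases and fell in 0, again the same adjusted over the list alone (median 0.53, camera adjusted p = 0.00458; adjusted p = 0.686 with an estimated correlation). Stat1 rose by 1.17 and Irf9 by 1.04, both transcription factors of the interferon response, while Irf7 was at -0.34 and Trim25 at -0.30.

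Genes of resting and follicular B cells were lower as a list, with 6 of 28 fallen and 2 risen, the same adjusted over the list alone (median -0.22, camera adjusted p = 0.0492; adjusted p = 0.686 with an estimated correlation). Tsc22d3, a glucocorticoid-induced leucine zipper, was 2-fold lower and S1pr1, a receptor for lymphocyte exit from tissues, 1.74-fold lower. Cr2, Foxo1, Ccr7 and Ripor2 were the other members that fell. S1pr4, another receptor of the same ligand, rose 2.7-fold and Rasgrp2 1.48-fold. The call of this list was lost with a pseudocount of 0.5 and without the lowest 25% of regions. It was also lost with only regions with mean H3K27ac above mean input and with regions given to the gene with the nearest end. Without any 1 H3K27ac library, 5 or 6 lists were higher and 0 to 2 lower, but at most 1 of the 56 called genes named from the lists kept its own call.

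**Figure D3:**
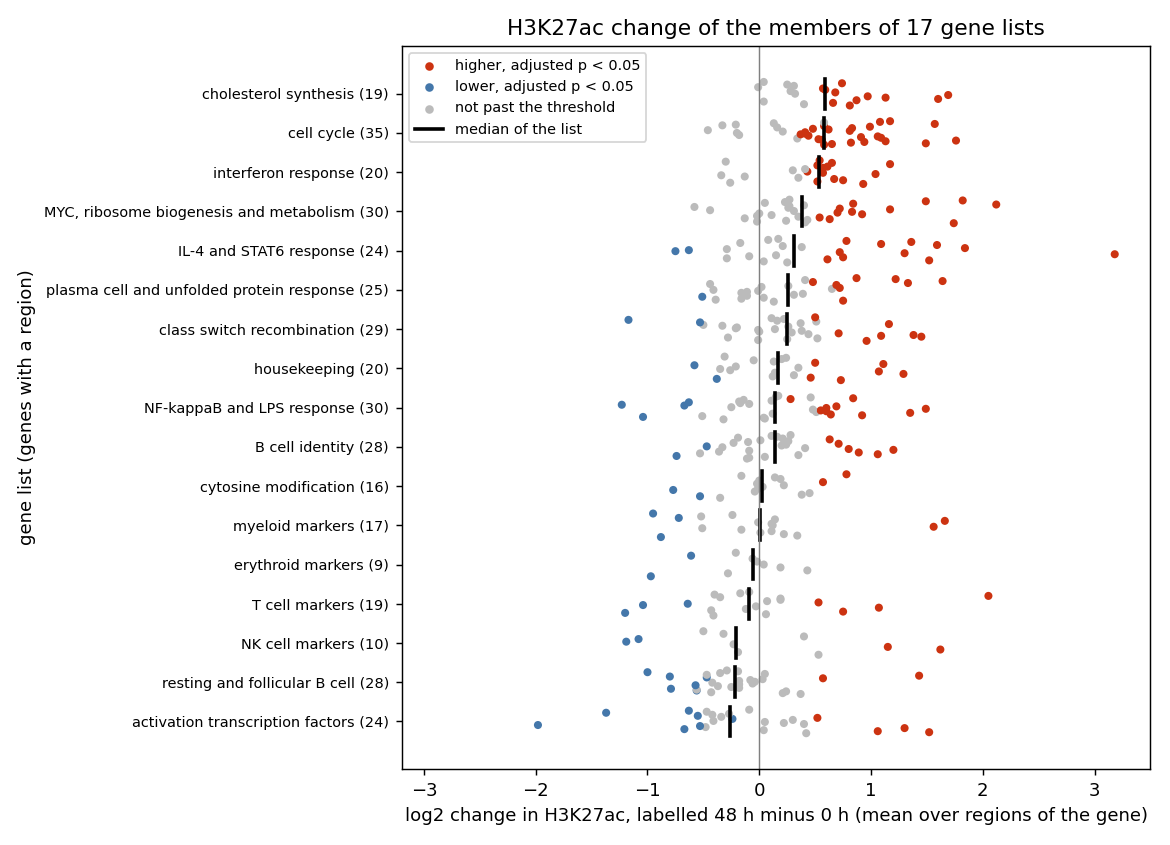
Log2 change in H3K27ac (libraries labelled 48 h minus 0 h) of each measured gene of the 17 lists, with the list median as a black bar; red and blue points passed an adjusted p of 0.05 over all genes. Medians range from 0.59 for cholesterol synthesis to -0.26 for activation transcription factors.

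The class switch recombination list did not pass as a set (median 0.25, camera adjusted p = 0.118), and 7 of its 29 genes rose and 2 fell (6 and 1 adjusted over the list alone). H2ax, the histone variant that marks DNA breaks, rose by 1.45 and Ighg1, the constant region of IgG1, by 1.38. Aicda itself rose by 0.96 over its regions (adjusted p = 0.00131), and Rad50, Ighe, Ighm and Xrcc6 also rose. Ung, the uracil glycosylase that acts after AID, was 2.25-fold lower and Rnf168 1.45-fold lower; the latter was 0.22 at the region with the highest value, which turned its direction. Plasma cell and unfolded protein response genes had 8 of 25 risen and Dnajc3 alone fallen (median 0.26, camera adjusted p = 0.167; 9 and 2 adjusted over the list alone). Among them Ssr3 rose by 1.64, Sdf2l1 by 1.33 and Xbp1, a transcription factor of secretory cells, by 1.22, while Sdc1 was at -0.44.

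Activation transcription factors went both ways, with 4 of 24 risen and 7 fallen (median -0.26, camera adjusted p = 0.24; 4 and 9 adjusted over the list alone). Those risen were Batf at 1.52, Egr2 at 1.30, Batf3 at 1.06 and Jund at 0.52. Fosb was 3.93-fold lower and the nuclear receptor gene Nr4a1 2.59-fold lower, and Egr1, Rel, Mafk, Fos and Junb also fell. NF-kappaB and LPS response genes had 10 of 30 risen and 4 fallen (median 0.14, camera adjusted p = 0.45; 11 and 4 adjusted over the list alone). Il6 rose by 1.49 and Ebi3, a cytokine subunit gene, by 1.35, while the genes fallen were Nfkbid, which was 2.34-fold lower, Ccl3, 2.05-fold lower, Nfkbib and Rel. B cell identity genes had 6 of 28 risen, led by the antigen receptor gene Cd79a at 1.20 and Cd22 at 1.06, and Btk and Fcrla fallen (median 0.14, camera adjusted p = 0.378; 6 and 2 adjusted over the list alone). Btk was at -0.74 but at 0.30 at the region with the highest value, and Cd24a was at -0.53 (adjusted p = 0.069). Of 16 genes of cytosine modification, Uhrf1 at 0.78 and Mbd4 at 0.57 rose, and Gadd45a at -0.77 and Cxxc5 at -0.53 fell, with the same counts adjusted over the list alone (median 0.02, camera adjusted p = 0.864); Gadd45a was at 0.32 at the region with the highest value.

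Markers of other spleen cells did not move together. Of 19 T cell markers, Thy1 at 2.05, Cd8b1 at 1.07, Cd4 at 0.75 and Il2ra at 0.53 rose, and Cd3d at -1.20, Gata3 at -1.04 and Icos at -0.64 fell (median -0.09, camera adjusted p = 0.45; 4 and 5 adjusted over the list alone); Gata3 was at 0.00 at the region nearest its end. Of 10 NK cell markers, Gzmb at 1.62 and Il2rb at 1.15 rose and Klrd1 at -1.19 and Klrk1 at -1.08 fell (median -0.21 and mean 0.02, camera direction down, adjusted p = 0.864; 2 and 2 adjusted over the list alone). Of 17 myeloid markers, Fcgr3 at 1.66 and Csf3r at 1.56 rose and Tyrobp at -0.95, Adgre1 at -0.88 and Itgax at -0.72 fell (median 0.01 and mean 0.02, although camera gave the direction down, adjusted p = 0.656; 2 and 3 adjusted over the list alone). Of 9 erythroid markers, Ermap at -0.97 and Tal1 at -0.61 fell and 0 rose (median -0.06, camera adjusted p = 0.45; Ermap alone fell adjusted over the list alone); Hbb-bs was at 0.43 and Hemgn at 0.19, and Tal1 was at 0.08 at the region with the highest value. Of 20 housekeeping genes, 6 rose, among them Gapdh at 1.29 and Rpl13a at 1.11, and B2m at -0.38 and Rab7 at -0.58 fell (median 0.17, camera adjusted p = 0.236; 6 and 2 adjusted over the list alone).

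The input libraries gave the background. In a fit of all 8 libraries, H3K27ac was higher than input in 3704 regions and lower in 4245 at 0 h, and higher in 5408 and lower in 5521 at 48 h (limma, adjusted p below 0.05). Because H3K27ac and input were brought to the same distribution, these counts describe relative positions within libraries and not absolute enrichment. The input libraries alone gave 0 regions that differed between 48 h and 0 h (limma, 2771 at an unadjusted p below 0.05; 0 and 6467 in the fit of all 8 libraries). The 0 h count of higher regions was 1320 without H3K27ac replicate 1, 416 without H3K27ac replicate 2, 5675 without input replicate 1 and 1318 without input replicate 2. At 48 h the count of higher regions fell to 2506 without H3K27ac replicate 1 and to 1072 without H3K27ac replicate 2.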

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

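Of the tests in this part, the comparisons of library pairings, the test of an exchange of both groups and that of the 2 input pairs were chosen after the result was seen. H3K27ac was tested against input for a difference in change from 0 h to 48 h, by the interaction contrast of the limma fit of all 8 libraries. In 1414 regions the H3K27ac change lay above the input change and in 1133 below it, at an adjusted p below 0.05 (13732 regions at an unadjusted p below 0.05). Leaving out a library moved these counts: to 678 and 328 without 0 h H3K27ac replicate 1, 498 and 415 without replicate 2, 480 and 577 without 48 h H3K27ac replicate 1, which turned the balance, 406 and 330 without replicate 2, and 2050 and 1697 without 0 h input replicate 1. At the Aicda locus the difference, on the log2 scale, was 2.25 for the region 4799 bp from Aicda, 1.74 for the region over Aicda and 1.75 for the long region over Mfap5. At the other 4 regions called higher there, which started at 122518950, 122519736, 122522068 and 122539288, the change did not pass against input (adjusted p = 0.593, 0.134, 0.145 and 0.2). Of all called regions, 1359 of the 7611 higher and 1090 of the 6958 lower passed against input in the same direction. The 24 named regions were picked as the largest changes in the same libraries, and 21 of them differed from input. The differences for the rises were 3.39 nearest Csf3r, 3.13 nearest Slc31a2, 3.29 at Kctd1, 3.59 nearest Ercc6l2, 3.00 at Cldn13, 3.51 at Ep300, 3.60 at Glp2r, 2.88 at Marchf10, 3.59 nearest Shprh, 3.03 beside Auh, 3.07 at Lrrc7 and 2.90 at Nostrin. For the falls they were -3.22 nearest Fosb, -3.30 nearest Cmc2, -2.74 at Asph, -3.03 at Il1r1, -2.77 at Ebf3, -2.82 nearest Rhou, -2.56 at Asmt, -3.28 nearest Rasgef1b and -2.53 nearest Adgrd1.

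Input itself shifted in the direction of H3K27ac. Its median log2 change was 0.16 over regions called higher and -0.10 over regions called lower, although 0 regions were called in input alone (limma, 2771 at an unadjusted p below 0.05). Region length as the whole cause is argued against, because the gap between the medians was at least 0.22 in each of the 5 length classes. A single deviating input pair is argued against as well, since the gap was 0.30 for replicate 1 and 0.22 for replicate 2. Preferential recovery of open chromatin in sonicated input or a biological difference in accessibility between the groups may give such a shift. H3K27ac reads within input libraries may give it as well. Pearson's r of 0 h input replicate 1 was 0.934 and 0.926 with the 0 h H3K27ac libraries and 0.928 with 0 h input replicate 2. For 0 h input replicate 2 it was 0.893 and 0.876 with these H3K27ac libraries. But 0 h input replicate 1 also had r of 0.922 and 0.909 with the 48 h H3K27ac libraries. With the 48 h input libraries it had 0.94 and 0.929, so its high r was not particular to 0 h H3K27ac. These explanations were not tested and stay open.

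The library names in the descriptions conflict with the titles in 4 samples, so a mislabelled sample may be in the table. If the names were right for the table columns, H3K27ac libraries sharing a condition by name would correlate best. Across regions, which are not independent replicates, Pearson's r of the log2 values was 0.957 and 0.963 for pairs by title and 0.899 and 0.896 for pairs by library name, and the difference of the means was 0.062 in favour of the titles. The split by title called 14569 regions, and each of the other 2 splits of the 4 libraries called 0. This argues against the pairing by library name for the H3K27ac libraries. For input, r was 0.928 and 0.924 for pairs by title and 0.94 and 0.917 by library name (difference of the means -0.003), so for the input libraries the labels cannot be told apart by correlation, as the pairs of a pairing differ by more than the pairings. Pairs by library name also share a replicate number, so a higher r by name could come from a replicate effect as well. An exchange of the titles of both H3K27ac groups as a whole would leave these correlations as they are. Such an exchange would make the libraries labelled 48 h those of resting cells, with lower cell cycle genes. The cell cycle list had a median log2 change of 0.58 in the libraries labelled 48 h (mean 0.61, standard error 0.09 over 35 genes), with 25 genes higher and 0 lower. The change was 3.18 (standard error 0.07) at Cish, 2.75 (0.17) at the long region of Ighg1 and 3.01 (0.20) at the region 4799 bp from Aicda. As each was the largest rise of its list or locus in these libraries, they add no separate evidence. The cell cycle list was itself chosen for this test after its values were seen, and its genes share the same libraries. It had the smallest camera adjusted p of the lists (1.9e-06). Of the lists named for activation or the stimulus, IL-4 and STAT6 response rose as a set (median 0.31, camera adjusted p = 0.00458). NF-kappaB and LPS response (0.14, 0.45) and activation transcription factors (-0.26, 0.24) did not pass. The cell cycle genes were thus higher, as the titles would have it, but a list picked in this way cannot decide on an exchange of both groups. The biological difference that the titles name, activation for 48 h, stays among the open explanations of the pairing by title.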

How the results depend on the processing

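The alternatives with H3K27ac above input only, without the libraries with conflicting names, with libraries left out of the fit of all 8, with regions given to the nearest gene end and with the lower-coordinate cluster were chosen after seeing the data. Of 2440 values recomputed over 33 settings, 1785 kept their direction and side of the threshold, 553 lost the call or fell by over 1.5 times, 41 gained, 54 turned and 7 ranks moved; the cause was not tested unless stated. Depth is unknown and limits low regions most. The counts of 7611 regions higher and 6958 lower became 2418 and 1436 without a mean trend, 10718 and 10466 with robust eBayes, 1677 and 946 against a 1.5-fold change, 5261 and 4370 with all 8 libraries, 2542 and 1966 with H3K27ac above input (fewer regions), 374 and 441 without the conflicting names (1 H3K27ac library per group, so that the input libraries alone gave the spread), and 0 and 0 when grouped by library name or without any 1 H3K27ac library. With an H3K27ac library left out of the fit of all 8 they were 1963 to 2546 and 1343 to 1996. Median centring gave 6608 and 8271, and leaving out the lowest 50% of regions 8182 and 8517, with more regions lower than higher. Without a trend, 3727 of the 14569 calls remained. A library left out leaves a group with 1 library, which is assumed to vary like the other.

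By Fisher's exact test, the odds ratio of 1.38 lost its call without a trend (1.2, p = 0.0625) and against a 1.5-fold change (1.16, p = 0.138), and was 0.895 to 1.56 with libraries left out of the fit of all 8, where 0.895 (p = 0.157) and 1.06 (p = 0.492) did not pass. The 7 Aicda regions became 4 against a 1.5-fold change, 1 with H3K27ac above input, 3 without the conflicting names, 0 by library name, 0 with libraries left out of the fit of H3K27ac alone, and 4 to 5 with libraries left out of the fit of all 8 (7 with none left out). Lists higher (5) were 2 with H3K27ac above input, 8 with the highest region, 0 with an estimated correlation and 0 by library name. Lists lower (1) were 0 with a pseudocount of 0.5, without the lowest 25%, with H3K27ac above input, with an estimated correlation and with the nearest end, 2 with the region nearest an end, 2 with the highest region, 4 by library name and 0 to 2 with libraries left out. With libraries left out, H3K27ac over input ranged at 0 h from 416 to 5675 higher and 1342 to 5205 lower, at 48 h from 1072 to 6576 higher and 1953 to 6520 lower, and the difference of changes from 406 to 2050 above and 328 to 1697 below. The nearest cluster ranked 4067 and 4498 at 0 h and 48 h with a gap of 5 kb, the lower-coordinate cluster 10007 at 0 h, and with all regions kept 1116 and 469.

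Grouped by library name, no region or gene named here passed (adjusted p = 1 for each): the groups mix the titles, which brings many changes near 0, and the sign before rounding, or for lists the camera direction, was opposite for Csf3r 0.00, Ercc6l2 -0.44, Ep300 -0.03, Glp2r -0.35, Shprh -0.20, Auh -0.02, Lrrc7 0.00, Nostrin -0.12, Ldlrad3 1.03, Rhou 0.25, the Mfap5 regions -0.63, -0.03 and -0.02, the Aicda region -0.25, the list medians of IL-4 -0.05, NF-kappaB -0.11, MYC 0.05, cholesterol -0.01 and interferon 0.01, and the genes Ighg1 -0.01, Ung 0.21, Cish -0.03, Il6 -0.46, Batf -0.01, Nr4a1 0.11, Rasgrp2 -0.13, Cd22 -0.05, Shmt2 -0.02, Sdf2l1 0.00, Idi1 -0.18, Fdps -0.15, Stat1 -0.17, Thy1 -0.04, Gata3 0.10, Gzmb -0.08, Il2rb -0.08, Fcgr3 -0.06, Tal1 0.20 and B2m 0.06. At the region nearest an end, Rnf168 0.22, E2f3 0.71, Psat1 0.86 and Gadd45a 0.32 turned and Gata3 was 0.00, and at the highest region Rnf168 0.22, Btk 0.30, Mki67 1.16, E2f3 0.71, Psat1 0.86, Gadd45a 0.32 and Tal1 0.08. Tal1 was also 0.08 without the lowest 50% of regions and with H3K27ac above input.

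Replicate numbers paired the libraries weakly at most. Across regions, the deviations of replicate 2 from 1 correlated at 0.15 between the 2 H3K27ac pairs and 0.03 for input. The labels name no shared batch. With a replicate block, 8519 regions were higher and 8210 lower, more than without it. Grouping by library name sets replicate 1 against replicate 2, so a grouping by name and a replicate effect are the same split here.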

Other observations

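Of the tests in this part, that of the Igh D segments was chosen after the result was seen, and the list of handling response genes was written before its values were examined, except that of Nfil3, a member of the IL-4 list. The Igh constant-region locus on chromosome 12 was looked at after its values were seen. The region of 15574 bp from 113329832 to 113345406, which overlaps Ighg1, rose most there, from 175.5 ± 2.12 to 1205 ± 298 (SD, n = 2 each), 6.73-fold with an adjusted p of 0.000846 by limma. The region from 113271955 to 113279986, which overlaps Ighe, rose 3.18-fold from 111 ± 1.41 to 356.5 ± 40.3 (adjusted p = 0.00133). IgG1 and IgE are the classes to which lipopolysaccharide with interleukin 4 is known to direct switching. The region of 47720 bp from 113220477 to 113268197, which overlaps Igha, rose 2.05-fold (adjusted p = 0.0014 by limma). Its change exceeded that of input by 0.82 (adjusted p = 3.36e-05). The region from 113412829 to 113430094 over Ighm and Ighd rose 1.71-fold (adjusted p = 0.013), a change that did not pass against that of input (difference 0.59, adjusted p = 0.0766). A short region from 113280696 to 113281420, 5969 bp from Ighg2c, rose 2.37-fold from 8 ± 0 to 20.5 ± 3.54 (adjusted p = 0.0365; 0.594 against input). The region from 113361526 to 113367839 beside Ighg3 had 154 ± 5.66 and 201 ± 8.49 (adjusted p = 0.0795), and that from 113308763 to 113318359 beside Ighg2b had 208.5 ± 26.2 and 238.5 ± 19.1 (adjusted p = 0.365). Whether the classes differ in their change was not tested. The change at Ighg1 exceeded that of input by 2.39 and that at Ighe by 1.37 (limma, adjusted p = 0.0163 for Ighe). Input at Ighg1 went from 710.5 ± 110 to 910.5 ± 99.7. Input at the Ighe region went from 338.5 ± 36.1 to 421.5 ± 95.5, so mean H3K27ac there lay below mean input at both times.

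Input was low over the Igh D segments. In the 5 regions between 113448214 and 113526809, the interval of D segments upstream of Ighd4-1, mean input was 0.0788 to 0.174 of the median of regions of similar length (median ratio 0.145), while H3K27ac in the same regions was 0.6 to 1.06 of it. A candidate explanation is the loss of germline D segment DNA by V(D)J recombination, which joins a D to a J segment in B cells. As a comparison, 2 regions over the D and J segments of the T cell receptor beta locus, which B cells do not rearrange as a rule, had ratios of 0.857 and 1.15. This is a hypothesis from 5 regions, and why H3K27ac was not lowered alike was not tested.

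Of the activation transcription factors, Fosb, Nr4a1 and 5 others had less H3K27ac in the libraries labelled 48 h, while Batf, Egr2, Batf3 and Jund had more, and the list did not pass as a set (camera adjusted p = 0.24). A handling response of the 0 h cells before fixation may give the lower values. A separate list of 23 genes known to respond to cell handling and stress, of which Nfil3 also belongs to the IL-4 list, had a median log2 change of -0.13, with 8 genes lower and 5 higher at an adjusted p below 0.05 (camera direction down, p = 0.0792; p = 0.192 with an estimated correlation). Hspa1a at -1.14 and Klf4 at -1 were lowest, and Nfil3 at 1.59 and Sik1 at 0.90 highest. The members went both ways, so a handling response and a biological loss of the mark during activation cannot be told apart here.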
